A study of Mus musculus with 4 samples.

How the data were processed

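Gene expression was measured with whole-transcript GeneChip arrays in 4 samples of plasmacytoid dendritic cells (pDCs) sorted from mouse spleens, 2 from wild-type (WT) and 2 from Flt3 knockout (Flt3 KO) animals. Per the labels, the spleens were digested with collagenase and DNase, the mice were at steady state, total RNA was amplified with an Ambion expression kit and labelled with biotin, and the samples of a genotype were biological replicates. The labels do not say whether a replicate was 1 animal or a pool, so the p-values below measure the spread between these samples.

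The deposited table holds the authors' processed intensity of 30177 probe sets on each of the 4 arrays, on a linear scale. The background correction, summarisation and scaling behind these intensity values are not given in the sources used here. The median deposited intensity was 55.1 and 55.3 in the WT arrays and 57.2 and 56.2 in the Flt3 KO arrays, and the maxima lay between 15496.2 and 16084.7, so the arrays were already on one scale to a close approximation. A constant residual difference in scale between the genotypes would move every log2 difference by the same amount. The residual was not constant. The upper quartile of intensity was 214.6 and 212.8 in the WT arrays and 206.2 and 209.5 in the Flt3 KO arrays, lower where the medians were higher. Its effect can therefore differ between bright and dim genes. No detection call accompanied the values, and for arrays it is the number of samples per group that limits the precision.

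Probe sets were named through the platform annotation, in which 21789 had a single gene symbol, 1621 had several and 6767 had none. Of the 21789, 21698 had a gene identifier found in the RefSeq gene table of the GRCm38.p6 assembly, and no symbol needed updating. That table was used for names and for the order of neighbouring genes only, because no genome build is named for the arrays, and no coordinates are given. Probe sets with a single symbol represented 19938 genes, of which 999 had more than 1 probe set; the probe set with the highest mean over the 4 arrays was kept for each gene. Probe sets with several symbols or none were left out of the comparison and entered an alternative in which all 30177 probe sets were tested together.

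Intensities were converted to log2 without an added constant and without a filter on dim genes. The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with no covariate. A difference is Flt3 KO minus WT on the log2 scale, its standard error (SE) is limma's moderated one, and p-values were adjusted by the Benjamini-Hochberg method over the 19938 genes. The threshold was an adjusted p under 0.05. With 2 samples against 2, an exact two-sided permutation test of a single gene cannot go below 0.3333, so each call rests on the variance that limma shares across genes.

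Gene lists were written before the data were examined, 15 of pathways, chromosomal neighbourhood and sex and 12 of markers of other cell types, with 698 entries of which 623 were measured. The first group held pDC identity genes, endosomal Toll-like receptor (TLR) signalling, interferon-stimulated genes, growth factor and cytokine receptors, feedback genes of STAT and MAPK signalling, apoptosis regulators, cell cycle genes, immediate early and heat shock genes, MHC class II presentation, homing receptors, endoplasmic reticulum (ER) and secretory genes, oxidative phosphorylation, cytosolic ribosomal proteins, the neighbours of Flt3 and sex-linked genes. The second held markers of B cells, plasma cells, T cells, NK cells, type 1, type 2 and both types of conventional dendritic cells, monocytes and macrophages, neutrophils, erythroid cells, platelets and megakaryocytes, and haematopoietic progenitors. The 26 lists with at least 5 measured members were tested with limma's camera, which compares a list with all other genes, at a preset correlation between genes of 0.01. The p-values were adjusted over the 26 lists. Camera was repeated with the correlation estimated from the arrays, and fry was run in addition; fry asks whether the genes of a list move one way on balance and does not compare the list with other genes. For each list the members past the threshold were also counted after adjustment over the list alone.

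The rule for naming genes, set at the same time, takes Flt3; the 12 genes with the largest positive and the 12 with the largest negative difference among those past the threshold whose replicate values did not overlap between genotypes; of each list up to 6 members past the threshold adjusted over the list alone, by adjusted p, and otherwise the 3 with the lowest p; and a few genes always shown (Siglech, Bst2, Tcf4, Irf8, Tlr7, Tlr9, Ccr9 and Ly6d among pDC genes, and Csf1r, Kit, Csf2ra, Il7r and Il3ra among receptors). Predicted genes, antigen receptor segments and similar unnamed types were counted but not named. Genes named outside this rule are marked as chosen after their values were seen.

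Alternatives fixed in advance were centring of each array on its median, quantile normalization over all rows, leaving out genes under the 40th percentile of mean log2 value, the mean of a gene's probe sets, eBayes without the trend or with robust variance, the replicate number as a block, 16 added to the intensity before log2, leaving out each array in turn, an adjusted p under 0.1, a plain rule of a 2-fold difference without overlap, camera with an estimated correlation and fry. Testing all probe sets of the table together, counted over the probe set kept for each gene or over all probe sets with a single gene, was added after the data had been seen. The replicate numbers in the labels were not treated as pairs, since nothing states what they share.

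The procedure was tested on simulated data with the gene means and spreads of these arrays, 200 genes changed among 19938, in 10 simulations with independent errors. Of the changed genes, 33.1% were found at a log2 change of 0.5, 95.1% at 1 and 100% at 2, and 4.67% of calls were unchanged genes. In addition the pDC identity genes were lowered by 0.2. That list was found in 10 of 10 simulations with the preset correlation and in 0 with an estimated one. A failure with an estimated correlation therefore decides little. Of 250 unshifted lists 1 was called, though some shared members with the shifted list, such as Tlr7 and Tlr9. That count does not cover correlated genes, and estimated correlations in these arrays reached 0.50 for MHC class II genes and 0.46 for monocyte and macrophage markers. Tables were joined with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1.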

Results

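Plasmacytoid dendritic cells, a dendritic cell type known for its large output of type I interferon, were profiled from the spleens of WT and Flt3 KO mice to compare gene expression with and without Flt3. Flt3 encodes the receptor tyrosine kinase for FLT3 ligand, a cytokine that drives dendritic cell development. Each genotype was represented by 2 samples, each hybridised to its own array. The log2 profiles of replicates correlated across genes with a Pearson r of 0.997 in both genotypes, and profiles of different genotypes with 0.994 to 0.995; genes are not independent replicates. The standard deviation (SD) of gene-wise log2 differences was 0.157 between the WT arrays and 0.169 between the Flt3 KO arrays, against 0.212 to 0.227 between arrays of different genotype. The first principal component held 68.4% of the variance and separated the genotypes, with scores of −11.4 and −9.65 in WT and 10.1 and 10.9 in Flt3 KO.

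Flt3 (Entrez gene 14255) itself was read by a single probe set, which gave log2 intensities of 10.71 and 10.77 in the WT replicates and 8.46 and 8.61 in the Flt3 KO replicates. The signal fell by 2.21 on the log2 scale (SE 0.066), a 4.61-fold difference, with a limma adjusted p of 7.4e-05. The remaining signal lay above 5.89, the median of all genes. The sources used here do not say which part of the gene the allele lacks or which exons the probes cover, so the residual signal cannot be assigned to intact transcript. Without WT replicate 1 or WT replicate 2 the Flt3 difference was −2.24 or −2.17 but its adjusted p rose to 0.0633 or 0.0736.

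In all, 476 of 19938 genes passed the threshold, 215 higher and 261 lower in Flt3 KO pDCs. Most differences were modest: the median absolute log2 difference of the 476 genes was 0.52, and 39 of them differed at least 2-fold, 29 higher and 10 lower. At an unadjusted p under 0.05 there were 3405 genes, where chance would give 996.9. Replicate values did not overlap between genotypes for 9419 genes or 47.2%, against 33.3% by chance. In 174 of the 215 higher genes (80.9%) Flt3 KO replicate 2 exceeded Flt3 KO replicate 1, compared with 51.0% of all genes, and the median gap was 0.13; among the lower genes it did so in 123 of 261. In 181 of the 261 lower genes (69.3%) WT replicate 1 exceeded WT replicate 2, compared with 49.6% of all genes; among the higher genes it did so in 111 of 215. The balance of higher and lower genes depended on scaling, with 217 higher and 452 lower after centring of each array on its median and 293 higher and 259 lower under quantile normalization. With a single array left out the limma fit had 1 residual degree of freedom: 0 genes passed without WT replicate 1 and 0 without WT replicate 2 (2068 and 2650 at an unadjusted p under 0.05), 54 without Flt3 KO replicate 1 and 2 without Flt3 KO replicate 2. All 476 genes kept their sign in these fits, and the calls of single genes given below were likewise lost in most of them, for 78, 78, 58 and 76 of the 78 named genes past the threshold. The differences of these 78 genes moved by less than 1.5 times in the 4 fits, whereas 16 of the 57 other named genes moved by more in at least 1 of them. Genes pass the threshold when their replicates lie close relative to the difference. The kept signs and small moves therefore follow from the selection and are no further support. With all arrays kept and no block, calls were also lost for Eps8l1 and Dusp1 with robust variance, Ly6d under quantile normalization, Dpp4 under centring, Irf7 with 16 added to each intensity, and Socs3 and Spred2 with probe sets averaged. Without the intensity trend 108 genes passed, and 47 of the 78 named calls were lost. With all 30177 probe sets tested together, an alternative added after the data had been seen, the probe sets kept for 219 of the 19938 genes passed.

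The gene with the largest rise among named genes was Ifi44l, an interferon-induced gene, from 4.74 ± 0.05 in WT to 7.19 ± 0.01 in Flt3 KO (mean log2 ± SD, n = 2 each). Its difference was 2.45 (SE 0.085, adjusted p = 0.00011); no fold is given because the WT level lay below 5.89, the median of all genes, where signal over background is low. Il13ra1, a chain of the receptor for IL-4 and IL-13, rose by 1.45 (SE 0.13) and the C-type lectin gene Cd209e by 1.41 (SE 0.075). Further rises of 1.18 to 1.30 were seen for the transporter gene Abca9, the membrane protein gene Emp1, Tppp3 and the orphan receptor gene Gprc5c. The same range held the annexin gene Anxa1, Jchain, which encodes the joining chain of polymeric antibodies, Emilin2, the 4-1BB ligand gene Tnfsf9 and Sestd1. Sestd1 lay below 5.89 in both genotypes (4.70 in WT and 5.88 in Flt3 KO) and Abca9 in WT (4.94), so their signal over background was low there. After Flt3, the largest falls among named genes were in Hsd11b1, whose product regenerates active glucocorticoid (fell by 1.91, SE 0.11, adjusted p = 0.0019), Eps8l1 (fell by 1.55, SE 0.27, adjusted p = 0.036) and the lysophosphatidylserine receptor gene Gpr174 (fell by 1.36, SE 0.11, adjusted p = 0.0037). Gpm6b fell by 1.15, Hpgds, a prostaglandin D synthase of haematopoietic cells, by 1.04, and B3galt5 by 1.00. Fam169b, the semaphorin receptor gene Plxna2, Klk1b27, Dmwd and the IL-9 receptor gene Il9r fell by 0.92 to 0.98. Gprc5c had a second probe set, with a difference of 0.99 in the same direction, and Klk1b27 belongs to a family of near-identical kallikrein genes whose probes can share signal, so its value is uncertain. Beyond the named genes, 25 of the 476 were predicted genes, antibody segments or other unnamed types, 10 higher and 15 lower. Of 36 called genes with more than 1 probe set, 2 had probe sets of opposite sign.

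**Figure D1:**
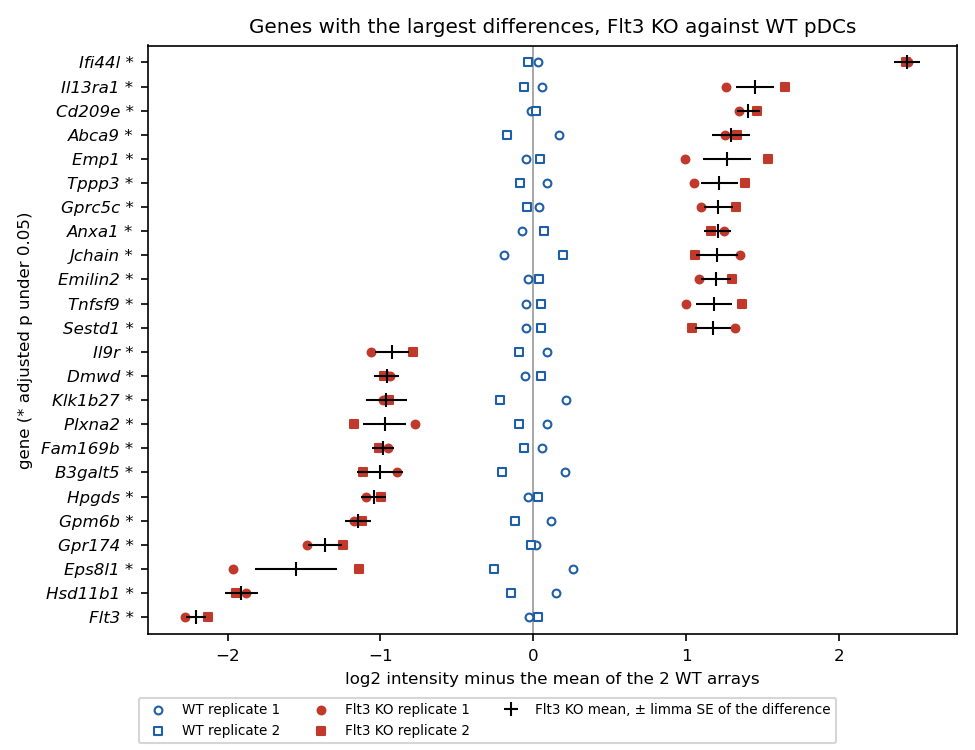
Log2 intensity of each array minus the mean of the 2 WT arrays (horizontal axis) for the 24 named genes of largest difference (vertical axis), with WT replicates as open and Flt3 KO replicates as filled symbols and a bar for the Flt3 KO mean ± the limma SE of the difference. Ifi44l lies 2.45 above and Flt3 2.21 below the WT mean, and the Flt3 KO replicates of Eps8l1 lie farthest apart, with an SD of 0.58.

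Genes that mark pDC identity were lower as a group. Of 36 measured, 14 fell, 1 rose and 21 did not pass the threshold, and the median difference was −0.24 (camera adjusted p = 5.4e-11; adjusted p = 0.38 with an estimated correlation). When adjusted over the list alone, 23 were lower and 1 higher. Fry also put the list past the threshold (adjusted p = 0.00016), and the median was −0.22 in Flt3 KO replicate 1 and −0.25 in replicate 2. The genes with the lowest adjusted p were Rpgrip1, which fell by 0.78 (SE 0.070), the phospholipid transfer protein gene Pltp (fell by 0.41, SE 0.041), the cytochrome c oxidase subunit gene Cox6a2 (fell by 0.76, SE 0.075), the single-stranded RNA sensor gene Tlr7 (fell by 0.49, SE 0.051), the chemokine receptor gene Ccr9 (fell by 0.43, SE 0.048) and the glutamate receptor gene Grm8 (fell by 0.49, SE 0.059). Irf8, a transcription factor gene of dendritic cell development, fell by 0.31 and Ly6d by 0.25. Other hallmarks of the lineage did not pass: the pDC lectin gene Siglech differed by −0.13 (adjusted p = 0.13), Bst2 by −0.074 (adjusted p = 0.35), the DNA sensor gene Tlr9 by −0.20 (adjusted p = 0.095), and Tcf4, the transcription factor gene that specifies pDCs, by −0.043 (adjusted p = 0.70), a difference whose sign turned under quantile normalization and without Flt3 KO replicate 1. Adjusted over the list alone, Siglech and Tlr9 were among the 23 lower genes, and Bst2 and Tcf4 were not. Siglech, Bst2, Tcf4 and Irf8 had mean log2 intensities of 12.52, 12.85, 12.21 and 11.99 in Flt3 KO cells. The one member that rose was the transcriptional corepressor gene Cbfa2t3, by 0.48, named here after its value was seen. Markers of monocytes and macrophages were higher in the same Flt3 KO arrays, as given below.

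**Figure D2:**
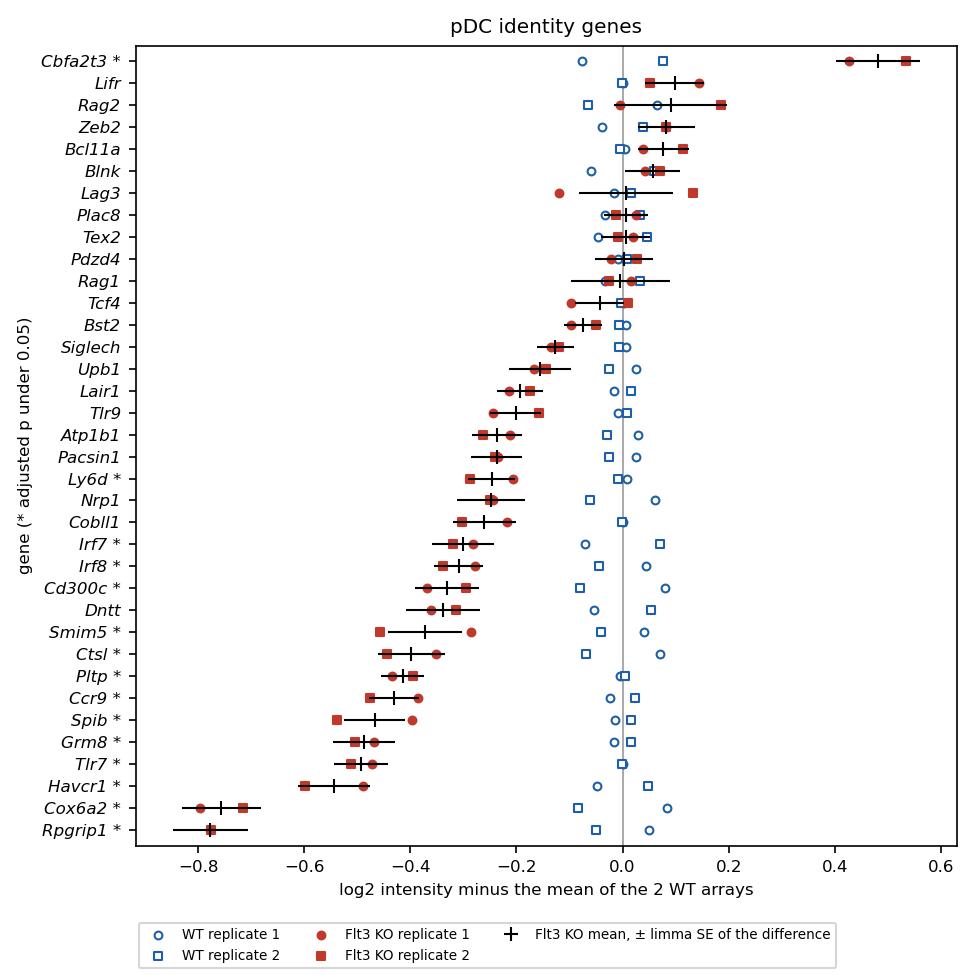
Log2 intensity of each array minus the mean of the 2 WT arrays (horizontal axis) for the 36 measured pDC identity genes (vertical axis), with WT replicates open, Flt3 KO replicates filled and the Flt3 KO mean shown with the limma SE of the difference. Asterisks mark the 15 genes past the threshold, 14 below and 1 (Cbfa2t3) above the WT mean, while Siglech, Bst2 and Tcf4 lie within 0.13 of it.

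The list of endosomal TLR signalling, which shares Tlr7, Tlr9 and Irf7 with the pDC list, had a median difference of −0.15 over 17 measured members (camera adjusted p = 0.0010; adjusted p = 0.57 with an estimated correlation; fry adjusted p = 0.028). Tlr7 and Irf7, the gene of the transcription factor that drives interferon-α production, fell, Irf7 by 0.30 with an adjusted p of 0.049995 at the edge of the threshold, and 15 did not pass. Another count, adjusted over the list alone, was 6 lower and 1 higher. Pld4, which encodes an endosomal nuclease, and the TLR chaperone gene Cnpy3 had differences of −0.25 and −0.21, and the adaptor gene Myd88 had 0.25, none past the genome-wide threshold.

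Interferon-stimulated genes were lower on balance, with a median of −0.11 over 33 measured (camera adjusted p = 0.00051; adjusted p = 0.57 with an estimated correlation). Oasl1 fell by 0.76 (SE 0.082), Usp18, which encodes a deubiquitinase-like brake on interferon receptor signalling, by 0.46, Ifi27l2a by 0.44 and Irf7 by 0.30; the remaining 29 did not pass, and none rose. Mx1 (−0.40) and Herc6 (−0.27) were among the 6 lower genes adjusted over the list alone, with 0 higher, where 9 were lower and 0 higher at an unadjusted p under 0.05 in limma. Interferon-induced genes that were not on the list went both ways. Ifi44l rose, and Ifitm1, Ifitm2 and Ifitm3 rose by 0.97, 1.12 and 0.95, while Gbp4, Gbp8 and Gbp9 fell by 0.89, 0.46 and 0.48. The Ifitm and Gbp genes are named after their values were seen. Ifi44l is also among the genes known to differ between mouse strains, given below. Without WT replicate 2 the list had an adjusted p of 0.057 and a median of −0.080, and without WT replicate 1 a median of −0.19.

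Among 28 measured growth factor and cytokine receptors, 3 rose and 1 fell. Il6st, which encodes the signalling chain gp130, rose by 0.83 (SE 0.071), the IL-6 receptor gene Il6ra by 0.80 (SE 0.13) and Il13ra1 by 1.45, while Il21r fell by 0.45 (SE 0.059). Other haematopoietic receptors did not pass: Csf1r had a difference of 0.52 (SE 0.16, adjusted p = 0.16), Kit 0.25 (SE 0.056, adjusted p = 0.080), Csf2ra 0.15 (adjusted p = 0.51), Il3ra 0.074 (adjusted p = 0.66) and Il7r −0.15 (adjusted p = 0.27). Tnfrsf1a differed by 0.31 (adjusted p = 0.12). Without Flt3 KO replicate 2, the array with the higher values of monocyte and macrophage markers, the differences were 0.28 for Csf1r, itself on that marker list, 0.19 for Tnfrsf1a, −0.087 for Il7r and −0.0084 for Csf2ra, whose sign turned; Csf2ra was at 0.31 without Flt3 KO replicate 1, and Il3ra ranged from 0.0097 to 0.14 with 1 array left out. The count was 7 higher and 2 lower adjusted over the list alone, and the median was 0.086 (camera adjusted p = 0.038; adjusted p = 0.58 with an estimated correlation). That call was lost without WT replicate 1 (adjusted p = 0.066), WT replicate 2 (0.18) or Flt3 KO replicate 2 (0.18, median 0.034), and without the intensity trend (0.053).

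Feedback genes of STAT and MAPK signalling moved both ways, and the list did not stand apart from other genes (median 0.039 over 23 genes, camera adjusted p = 0.97); camera leaned up and fry down. The ETS transcription factor gene Etv5 fell by 0.74 (SE 0.091), the cyclin gene Ccnd2 by 0.40 and the MAPK inhibitor gene Spred2 by 0.42, while the repressor gene Bcl6 rose by 0.42 and Socs3, an inhibitor of gp130 signalling, by 0.56 (SE 0.090). A second, dimmer probe set of Socs3 differed by 0.10, and the Socs3 and Spred2 calls were lost when probe sets were averaged. Adjusted over the list alone 4 were higher, Pim1 (0.45) among them, and 5 lower. Of 17 apoptosis regulators, the survival gene Mcl1 rose by 0.47 and the pro-apoptotic gene Bid fell by 0.54, also adjusted over the list alone, and 15 did not pass (median 0.045, camera adjusted p = 0.47). None of 33 cell cycle genes passed in limma, also adjusted over the list alone, and 1 had an unadjusted p under 0.05 (median −0.010, camera adjusted p = 0.97). The lowest p-values were those of Stmn1 (0.22), Tk1 (−0.15) and Tyms (−0.23), the last at −0.36 without Flt3 KO replicate 1 and −0.11 without Flt3 KO replicate 2.

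Markers of monocytes and macrophages had the highest median of the lists, 0.34 over 25 measured (camera adjusted p = 9.5e-08; adjusted p = 0.58 with an estimated correlation). The chemokine receptor genes Ccr2 and Cx3cr1 rose by 0.70 (SE 0.063) and 1.03 (SE 0.14), the fibronectin gene Fn1 by 0.88 (SE 0.096), the lipopolysaccharide co-receptor gene Cd14 by 1.08 (SE 0.16), and the lysozyme genes Lyz2 and Lyz1 by 0.51 and 0.48; these near-identical paralogs can share probe signal. There were 8 higher and 0 lower adjusted over the list alone, with 11 higher and 0 lower at an unadjusted p under 0.05 in limma. The Flt3 KO replicates differed in this list. Relative to the WT mean its median was 0.078 in Flt3 KO replicate 1, where 16 of 25 markers lay above the WT mean, and 0.54 in Flt3 KO replicate 2, where 22 did. Between the WT arrays the medians were 0.090 and −0.090. The complement genes C1qa, C1qb and C1qc, made by tissue macrophages, had log2 intensities of 9.42, 8.34 and 8.06 in Flt3 KO replicate 1 and 10.05, 8.74 and 8.67 in replicate 2, with WT means of 9.24, 8.20 and 7.93; none passed, and they are named after their values were seen. Without Flt3 KO replicate 2 the median was 0.078 with an adjusted p of 0.0051, without Flt3 KO replicate 1 it was 0.54, and without WT replicate 2 it was 0.21 (adjusted p = 0.0042).

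**Figure D3:**
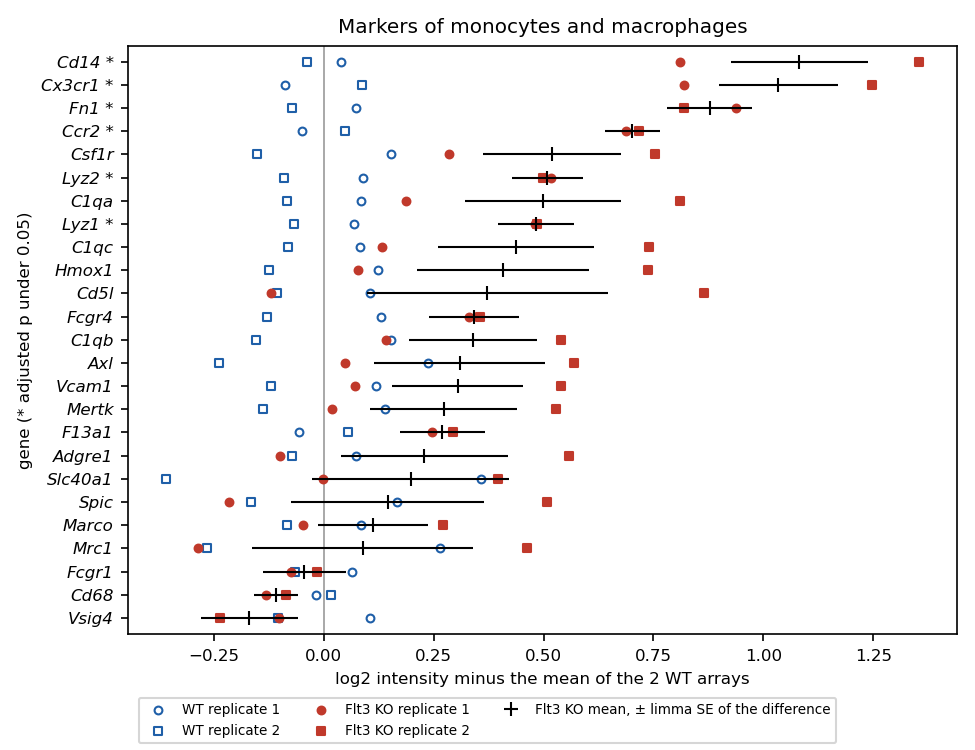
Log2 intensity of each array minus the mean of the 2 WT arrays (horizontal axis) for 25 markers of monocytes and macrophages (vertical axis), with WT replicates open, Flt3 KO replicates filled and the Flt3 KO mean shown with the limma SE of the difference. The 6 markers past the threshold, marked by asterisks, are higher in both Flt3 KO replicates, whereas C1qa, C1qc, Cd5l and Hmox1 are higher mainly in Flt3 KO replicate 2, the array with the list median of 0.54.

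Markers of type 2 conventional dendritic cells were split. Tmem176b, Tmem176a, Il1b and Cd300a rose by 0.90, 0.89, 0.97 and 0.64, while Cd4 and the lymphotoxin gene Ltb fell by 0.87 and 0.77. Cd4 and Ltb were bright in WT (10.54 and 8.89, against a list median of 7.73), so their signal need not come from type 2 cells. Rab7b (9.58), Fcrla (10.56) and Cd8b1 (10.49), lower members of other marker lists below, were bright in WT too. Of 20 measured, 5 rose and 3 fell, and adjusted over the list alone 9 were higher and 3 lower. The median was 0.15 (camera adjusted p = 0.019; adjusted p = 0.58 with an estimated correlation), 0.20 in Flt3 KO replicate 1 and 0.17 in replicate 2, and the call was lost without WT replicate 2 (adjusted p = 0.18, median 0.097) or Flt3 KO replicate 2 (adjusted p = 0.052). Among markers of both conventional types Nectin1 rose by 0.78 and Dpp4 by 0.29, and 18 of 20 did not pass (median 0.096, camera adjusted p = 0.064). Adjusted over the list alone 8 were higher and 2 lower, with Avpi1 (0.54), Btla (0.42) and Kit among the higher and H2-Eb1 among the lower. Of 19 markers of type 1 cells Rab7b fell by 0.54 and 18 did not pass, with Cd36 at −0.43 and Ifi205 at 0.72 (0.40 without Flt3 KO replicate 1); adjusted over the list alone 2 were lower and 1 higher. Its median was −0.014 and its mean 0.0097 (camera adjusted p = 0.97, direction down).

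Plasma cell markers had a median of 0.19 over 10 measured (camera adjusted p = 0.037; adjusted p = 0.57 with an estimated correlation). Slamf7 rose by 0.94 (SE 0.078) and Jchain by 1.20, while the ER foldase gene Txndc5 fell by 0.48; adjusted over the list alone 4 were higher, with Irf4 at 0.19 and Fkbp11 at 0.25, and 1 lower. The call was lost without WT replicate 1 (adjusted p = 0.084), WT replicate 2 (0.058) or Flt3 KO replicate 1 (0.14), and without the intensity trend (0.053). NK cell markers had a median of 0.13 over 19 (camera adjusted p = 0.0067; adjusted p = 0.57 with an estimated correlation); the activating receptor gene Klrk1 rose by 0.68, alone also adjusted over the list alone, and 18 did not pass. The median WT level of the NK cell markers was 5.03, below 5.89, the median of all genes, where signal over background is low. B cell markers had a median of −0.058 over 18 (camera adjusted p = 0.32). Fcrla fell by 0.54 and 17 did not pass; adjusted over the list alone 5 were lower and 2 higher, with Chst3 at −0.44, Cd79b at −0.25, Fcmr at −0.29, Cr2 at 0.35 and Ighm at 0.36. Probe sets of Ighm disagreed, with −0.18 and 0.64 for its dimmer ones. T cell markers had a median of 0.017 over 17 (camera adjusted p = 0.88): Cd8b1 fell by 0.26, 16 did not pass, and adjusted over the list alone 2 were lower, Cd5 (−0.36) in addition.

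No marker of platelets, haematopoietic progenitors, neutrophils or erythroid cells passed the threshold in limma. The median WT levels of these lists, 5.65, 5.56, 5.01 and 5.18, lay below 5.89, the median of all genes, where signal over background is low. The 11 platelet and megakaryocyte markers had a median of 0.16 (camera adjusted p = 0.0088; adjusted p = 0.57 with an estimated correlation), with 1 at an unadjusted p under 0.05, 0 adjusted over the list alone, and Ppbp, Tubb1 and Gp5 at 0.35, 0.24 and 0.25. Ppbp was at 0.24 without WT replicate 2 and 0.23 without Flt3 KO replicate 1, Tubb1 at 0.12 without Flt3 KO replicate 1 and Gp5 at 0.14 without WT replicate 1. The list's call was lost when dim genes were left out (adjusted p = 0.092), and the median was 0.26 without WT replicate 1. The 18 progenitor markers had a median of 0.096 (camera adjusted p = 0.037; adjusted p = 0.58 with an estimated correlation), 6 at an unadjusted p under 0.05 and 1, Kit, adjusted over the list alone. That call was lost without WT replicate 2 (adjusted p = 0.46, median 0.055), without Flt3 KO replicate 1 (adjusted p = 0.14, median 0.053) and under quantile normalization (adjusted p = 0.059). Neutrophil markers had a median of −0.0032 and a mean of 0.020 over 20 (camera adjusted p = 0.65, direction up), with 3 at an unadjusted p under 0.05 and 0 adjusted over the list alone; S100a8, Csf3r and Cxcr2 were at −0.34, 0.32 and 0.38. S100a8 was at −0.52 without WT replicate 1 and −0.17 without WT replicate 2, Csf3r at 0.18 without WT replicate 2 and 0.19 without Flt3 KO replicate 2, and Cxcr2 at 0.60 without Flt3 KO replicate 1 and 0.15 without Flt3 KO replicate 2. The 11 erythroid markers had a median of 0.042 (camera adjusted p = 0.97), with 4 at an unadjusted p under 0.05; adjusted over the list alone Ermap (−0.35) was lower and Tspan33 (0.34) higher.

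Immediate early and heat shock genes, which respond within minutes to stimulation or tissue handling, had a median of 0.20 over 29 (camera adjusted p = 3.6e-05; adjusted p = 0.57 with an estimated correlation). Klf4 rose by 0.44, Ier3 by 0.69, the MAPK phosphatase gene Dusp1 by 0.75 (SE 0.13) and the nuclear receptor gene Nr4a2 by 0.51, and 25 did not pass. Ier3 lay below 5.89, the median of all genes, in both genotypes (4.81 in WT and 5.51 in Flt3 KO), where signal over background is low. Adjusted over the list alone 10 were higher, Junb (0.33) among them, and 1 lower, Rgs1 (−0.56). The median was 0.20 in Flt3 KO replicate 1 and 0.17 in replicate 2, and it was 0.034 without WT replicate 2 (adjusted p = 0.028). MHC class II presentation genes went both ways: the endosomal protease gene Lgmn rose by 0.51 and H2-Oa fell by 0.46, and 13 of 15 did not pass. Adjusted over the list alone 4 were higher, with Cd40 (0.41) and Cd86 (0.51), and 5 lower, with H2-Eb1 (−0.19) and H2-Ob (−0.28). The list's median was −0.011 and its mean 0.046, and camera (adjusted p = 0.97) leaned down where fry leaned up; the median was −0.087 in Flt3 KO replicate 1 and 0.087 in replicate 2. Homing receptors were divided too, with Ccr2, Cx3cr1 and the chemerin receptor gene Cmklr1 (by 0.52) higher, Ccr9 and Cxcr3 (fell by 0.32) lower, and 15 of 20 not past the threshold. Of the 3 that rose, Ccr2 and Cx3cr1 are also on the list of monocyte and macrophage markers. Adjusted over the list alone 5 were higher, Ccr1 (0.73) among them, and 6 lower. Their median was −0.046 and their mean 0.089 (camera adjusted p = 1.00, direction up).

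Genes of the ER and secretory pathway had a median of −0.037 over 29 (camera adjusted p = 0.037; adjusted p = 0.69 with an estimated correlation). Herpud1 fell by 0.28, Mzb1 by 0.53 and the unfolded protein response gene Xbp1 by 0.25, and 26 did not pass; adjusted over the list alone 5 were lower, with Ssr4 (−0.24) and Edem2 (−0.25), and 0 higher, against 9 lower and 0 higher at an unadjusted p under 0.05 in limma. The list's call was lost without WT replicate 2 (adjusted p = 0.25, median −0.022), without Flt3 KO replicate 2 (adjusted p = 0.62, median 0.0056), under quantile normalization (0.25), with dim genes left out (0.20), with probe sets averaged (0.074) and without the intensity trend (0.078), and its median was −0.088 without WT replicate 1 and −0.092 without Flt3 KO replicate 1. Oxidative phosphorylation genes had a median of −0.096 over 33 (camera adjusted p = 0.0010; adjusted p = 0.58 with an estimated correlation). None passed in limma, also adjusted over the list alone, while 8 were lower and 0 higher at an unadjusted p under 0.05, Cox7b, Cox6c and Ndufa4 leading at −0.18, −0.17 and −0.18. The list had an adjusted p of 0.058 without WT replicate 2 and a median of −0.064 without Flt3 KO replicate 1. None of 43 cytosolic ribosomal protein genes passed in limma, also adjusted over the list alone, and 2 were lower at an unadjusted p under 0.05 (median −0.011, camera adjusted p = 0.88), with Rps14, Rpl34 and Rps29 at −0.11, −0.12 and −0.094 (Rps29 at −0.058 without WT replicate 1).

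Camera called 13 of the 26 lists, 8 higher and 5 lower in Flt3 KO. None of the 13 passed with an estimated correlation, where the lowest adjusted p was 0.38 and 1 list had an unadjusted p under 0.05. In the simulations that test found a list shifted by 0.2 in 0 of 10, so its failure cannot decide about these calls. The estimated correlation was −0.028 for pDC identity genes and −0.033 for endosomal TLR signalling, below the preset 0.01. Correlation was therefore not what ended those calls. Fry put 2 lists past the threshold, pDC identity and endosomal TLR signalling. Without WT replicate 2, 6 lists passed. In 6 lists the median differed in sign between Flt3 KO replicates 1 and 2: besides MHC class II genes, these were ER and secretory genes (0.0055 and −0.092), feedback genes (−0.052 and 0.0038), ribosomal protein genes (−0.023 and 0.0057), T cell markers (0.089 and −0.0066) and erythroid markers (0.080 and −0.076).

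**Figure D4:**
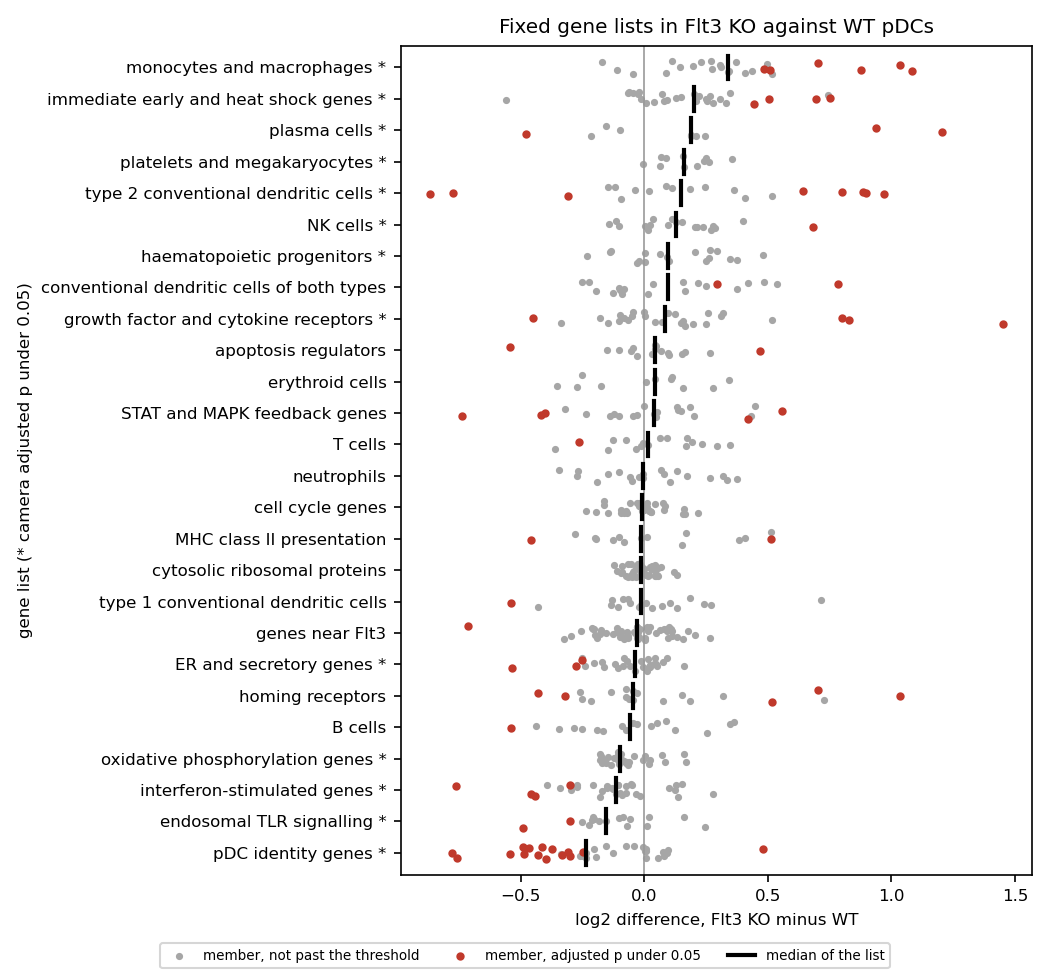
Log2 differences, Flt3 KO minus WT (horizontal axis), of the members of the 26 lists tested (vertical axis), with members past the threshold in red, other members in grey and a black bar for the median of each list. Medians run from −0.24 for pDC identity genes to 0.34 for markers of monocytes and macrophages, and asterisks mark the 13 lists past camera's threshold at the preset correlation.

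Genes beside Flt3 on its chromosome were examined because DNA flanking a targeted gene can differ between knockout and WT mice. Of 55 neighbours measured, B3glct fell by 0.71 (SE 0.11, adjusted p = 0.026), also adjusted over the list alone, and 54 did not pass (median −0.029, camera adjusted p = 0.17). Of the sex-linked genes 4 were measured and none passed in limma, at an unadjusted p under 0.05 either. The Y-linked genes Kdm5d, Eif2s3y and Uty lay between 7.13 and 7.85 in mean log2 intensity in both genotypes, and Xist at 4.56 in WT and 4.47 in Flt3 KO.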

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

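Rows of the array table that the comparison left out held signal of their own; they were tested together with all 30177 rows, an alternative chosen after the data had been seen, and 291 rows passed in all. Of 1621 probe sets with several gene names, 27 passed the limma threshold, 5 higher and 22 lower in Flt3 KO pDCs, a share of 1.67%. Of 6767 probe sets with no gene name, 32 passed, 10 higher and 22 lower, a share of 0.473%. In the same test 232 of 21789 probe sets with a single gene passed, 125 higher and 107 lower, a share of 1.06%.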

How the results depend on the processing

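The alternatives of testing all probe sets together were added after the data had been seen; the others were planned. The count of 476 genes stayed within 1.5 times under centring (669), quantile normalization (552), a filter on dim genes (668 of 11963), averaged probe sets (465), robust variance (598) and 16 added to each intensity (454), and 444 to 474 of the 476 genes were shared with each. It was 108 without the intensity trend, 886 at an adjusted p under 0.1, 42 under the 2-fold rule without overlap and 219 (all shared) when all 30177 probe sets were tested together and the 1 kept for each gene was counted. Counting instead every probe set with a single gene, another unit, gave 232, among them probe sets of 221 of the 476 genes. The causes beyond each setting's construction were not tested. With 1 array left out it ranged from 0 to 54, where the lone sample of a genotype is assumed to vary like the other group and 1 residual degree of freedom remains. The Flt3 difference ranged from −2.28 to −2.13 with 1 array left out, and passed the threshold in every setting that kept all 4 arrays. The 13 lists became 0 with an estimated correlation, 2 with fry, and 6 to 12 with 1 array left out; other settings gave 10 to 14. Tcf4 turned to 0.00050 under quantile normalization and ranged from −0.097 to 0.011 with 1 array left out, and Csf2ra ranged from −0.0084 to 0.31; the cause was not tested. For the 135 named genes, 964 of 1072 values in settings with all arrays kept their sign and their side of the threshold, 60 lost a call, 47 of them without the intensity trend, and 47 gained one. Markers of both types of conventional dendritic cells passed in 4 of these settings, with adjusted p-values from 0.021 to 0.048. Same-numbered replicates did not deviate together (correlation across genes −0.017). With 2 arrays per genotype this cannot exclude a shared day, litter or batch, and nothing states what the numbers share. With the replicate block in limma 375 genes (341 of them shared) and 14 lists passed. Of the named genes 4 gained a call and 6 lost it, Spred2 (adjusted p = 0.066), Xbp1 (0.053), Cd8b1 (0.068), Lyz1 (0.056), Irf7 (0.063) and Dpp4 (0.083). Dim genes limit these results: 43 of the 476 called genes lay below the median log2 value of 5.89, where signal over background is low.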

Other observations

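The gene families and tests in this part were chosen after the result, or some of the genes behind it, had been seen. The Ifitm family is named for interferon-induced transmembrane proteins, though not every member need be induced by interferon. Of 7 measured, 4 were higher in Flt3 KO pDCs, each in both Flt3 KO replicates. Ifitm1 rose by 0.97 (SE 0.089), Ifitm2 by 1.12 (SE 0.13), Ifitm3 by 0.95 (SE 0.13) and Ifitm5 by 0.48 (SE 0.092). Because that family was picked from its called members, all 632 beginnings of gene names with at least 5 measured genes were tested alike for their number of calls (one-sided Fisher's exact test against all genes, adjusted over the 632). Ifitm was 1 of 4 that passed (adjusted p = 0.0027), with Slamf (adjusted p = 0.021; Slamf7 and Slamf8 rose by 0.94 and 0.59 and Slamf6 fell by 0.36, of 5 measured) and the broad beginnings Cd and Il (adjusted p = 4.6e-10 and 0.0027), which join unrelated genes. The test counts members as independent, and its p for Ifitm is too small if related members share probe signal. Among 8 guanylate-binding proteins, an interferon-inducible family, Gbp4, Gbp8 and Gbp9 fell by 0.89, 0.46 and 0.48. The beginning Gbp did not pass in Fisher's exact test (adjusted p = 0.088). Cd300a rose by 0.64 while Cd300lf and Cd300c fell by 0.63 and 0.33, and 5 of 8 Cd300 genes did not pass; the family's median turned from 0.0088 to −0.029 under centring and −0.014 under quantile normalization. Klk1b27, Klk1b11 and Klk1b5 fell among 16 kallikrein 1 genes, and H2-Q5, H2-Q4 and H2-T10 fell by 0.67, 0.66 and 0.49 among 18 class Ib histocompatibility genes. In the 10 families counted, the numbers of called genes were the same under centring and quantile normalization, except under centring for class Ib genes (4 lower) and antibody chain genes (2 higher). Members of the Klk1b and H2-Q families are near-identical too, so the split between members is uncertain.

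Ms4a6c and Ms4a6b rose by 0.92 and 0.84, S100a10 and S100a4 by 0.57 and 0.87, and Anxa1 and Anxa5 by 1.21 and 0.50. Of their families 17 of 19 Ms4a genes, 16 of 18 S100 genes and 10 of 12 annexins did not pass, with medians of 0.044, 0.12 and 0.056, and of 23 killer lectin receptors 1, Klrk1, was higher. Fisher's exact test of called counts over the 10 families gave an adjusted p of 0.00011 for Ifitm, 0.0023 for the guanylate-binding proteins and for Cd300, 0.015 for kallikrein 1, 0.017 for class Ib genes, 0.053 for annexins, 0.093 for Ms4a and for S100, 0.32 for antibody chains and 0.43 for killer lectin receptors. All 10 were picked after some of their genes had been seen, so these p-values restate the pick and show no enrichment.

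Markers of monocytes and macrophages had the highest median difference of the lists, 0.34, with 6 of 25 past the threshold and a median over the WT mean of 0.54 in Flt3 KO replicate 2 and 0.078 in replicate 1, against 0.090 in WT replicate 1. A lower share of pDCs in the sort would raise markers of the cells that took their place, and it stays open. A mix of other cells would raise several marker lists. Monocytes or macrophages alone would raise only their own, so a list that stayed apart does not argue against a lower share. Of the 12 marker lists of other cells, 6 were called higher and 0 lower. The NK cell, platelet and progenitor lists among them had median WT levels of 5.03, 5.65 and 5.56. These lie below 5.89, the median of all genes, where signal over background is low, so the count is weak ground. Of the B cell and T cell lists 1, B cells, stayed apart from the monocyte and macrophage markers within a range of levels. The range ran from the median of all genes, reached in either genotype, to the 75th percentile of WT level. A marker could thus enter through its Flt3 KO level, as Fn1 did, so the lists were not matched on WT level. In that range 13 B cell markers had a median of −0.030 (95% bootstrap interval −0.17 to 0.13), 10 T cell markers 0.13 (−0.013 to 0.24), 7 NK cell markers 0.28 (0.21 to 0.40), 5 neutrophil markers −0.15 (−0.27 to 0.32) and 10 monocyte and macrophage markers 0.31 (0.15 to 0.48). The bootstrap, here and below, resampled markers and not arrays, so these intervals do not cover the spread between samples. For all 25 monocyte and macrophage markers the medians in the Flt3 KO arrays, 0.078 and 0.54, lay outside that interval. Monocytes or macrophages among the sorted cells, a case of such a lower share, remain open too. The 22 markers whose mean in either genotype reached the median of all genes had a median of 0.36 (0.27 to 0.49 over markers). Lyz2 rose by 0.51, and 3 of the 25 markers are shared with other lists. A change inside pDCs or a pDC-like subset would give the same, which was not tested. The part in tissue macrophage genes may come from Flt3 KO replicate 2, since the list median without it was 0.078 against 0.34, while Ccr2, Fn1, Lyz2, Cx3cr1 and Cd14 were higher in both replicates. Cd68 and Fcgr1, also on the list, differed by −0.11 and −0.044 and did not pass.

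Genes known to differ between mouse strains were among the calls. Nnt, which carries a deletion in the C57BL/6J strain, rose by 0.96 (SE 0.061, adjusted p = 0.0031; 8.06 and 8.01 in WT against 8.99 and 8.99 in Flt3 KO), and Ifi44l, also known as the minor histocompatibility gene H28, rose by 2.45. Sequence of another strain flanking Flt3 cannot be told apart from none, since 1.82% of its 55 neighbours passed (exact 95% interval 0.046 to 9.72) against 2.38% of other genes (Fisher's exact test p = 1), too few genes to decide. Stretches of another strain elsewhere may contribute: called genes without shared name beginnings were neighbours in 26 pairs, against a mean of 13.04 in 10000 random draws of as many genes (95% of draws 7 to 20.0, one-sided permutation p = 0.0012). Neighbours under shared regulation would give such pairs too, which was not tested, 21 of the 26 moved the same way, and neither Nnt nor Ifi44l was in a pair; the mice's background strains are not given in the sources used here.

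Jchain and a single kappa light chain segment were higher in the Flt3 KO arrays, by 1.20 and 1.81. That segment was the 1 of 14 measured antibody chain genes past the threshold (2 under centring), and the median of the 14 was 0.44. A large share of B cells among the sorted cells is argued against, because such cells would raise B cell markers as a group. The 17 B cell markers other than antibody genes had a median of −0.073 (95% bootstrap interval −0.25 to 0.054 over markers, not arrays). Over the whole B cell list the median was −0.032 in Flt3 KO replicate 1 and −0.11 in replicate 2. Fcrla, among the 17, was bright in WT (10.56), so its fall of 0.54 need not concern B cells. Of the 17, 16 had a lower signal than Jchain in WT. Signals of different probe sets do not rank transcripts, so a small rise could still be hidden. Cd79a, Ms4a1 and Pax5 differed by 0.026, −0.090 and −0.030. Plasma cells cannot be told apart from a change inside pDCs, since their 8 markers other than antibody genes and Jchain had a median of 0.19 with an interval of −0.22 to 0.25. Sdc1 and Tnfrsf17 differed by −0.15 and −0.22, and Txndc5 and Mzb1 fell by 0.48 and 0.53, while Slamf7 rose by 0.94. An effect of genotype inside pDCs stays open and was not tested.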
